A study of Mus musculus with 12 samples.

How the data were processed

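Total RNA of mouse splenic follicular B cells, purified from male C57BL/6J mice per the labels, was hybridised with Cy3 to Agilent one-colour arrays, 1 sample per array. The 12 arrays form 4 groups of 3 by genotype (WT or Bach2-/-) and time (0 h, or 24 h with 10 µg/mL anti-IgM Fab'), taken from the labels. Per the file headers, the authors' scanner images were read with Agilent Feature Extraction 10.7.3.1. Its processed signal is an intensity after local background subtraction, spatial and multiplicative detrending and replacement of low signals by surrogates, per the file headers. The median signal and median background, also intensities per the file headers, served in 1 alternative. Other columns used, per the file headers, were the flags for control spots, outliers, saturation and signal well above background. The deposited whole-series table holds log2 values whose scale and centring the sources used here do not state. Set against the scanner signals, they equal the log2 processed signal minus the 75th percentile of its array, with each probe's median over the 12 arrays set to 0 (Pearson r 0.9995 to 0.99996). Scale and centring were thus found from the values, the direction is that of the signal, and only the order of steps stays unknown. Its column medians were -0.040, 0.16 and 0.014 for WT 0 h, -0.27, 0.11 and 0.011 for WT 24 h, -0.26, -0.097 and -0.031 for Bach2-/- 0 h and -0.27, 0.50 and 0.071 for Bach2-/- 24 h.

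From the 59305 noncontrol spots of each array, those flagged as outliers (112 to 511 per array) were left out, and spots of 1 probe were averaged (399 probes have 10 spots). No tested probe had a saturated spot. The processed signal was divided by its array's 75th percentile, set to a floor of 0.01 and taken to log2. A probe was kept if well above background on all 3 arrays of at least 1 group (30751 probes), and each gene was represented by its probe with the highest mean. Of 55681 probes, 26413 were named through their RefSeq accession (20018 symbols; 25731 of 26273 curated mRNA accessions matched) with a table of assembly GRCm38.p6, and 29268 kept the name in the file. The array annotation is on build mm9 per the file headers, so no coordinates are printed. This left 22751 names, called genes here, of which 13140 have a RefSeq symbol. Of 3299 genes with several probes, probes of opposite sign occurred among 1, 1, 41, 27 and 0 called genes of the comparisons in the order of the report.

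Group means were fitted to all 12 arrays with limma 3.58.1 (R 4.3.3, data.table version 1.17.8, Python 3.11.15), with empirical Bayes variances (11.4 degrees of freedom). The 5 contrasts were genotype at 0 h and 24 h, the 24 h change (response) in WT and Bach2-/- cells, and the response difference. Genes passed at a Benjamini-Hochberg adjusted p under 0.05 over all genes, 2-sided. The smallest exact permutation p of 3 against 3 arrays is 0.1. A gene below background on every array of 1 group has only a bound: the bright group's mean against the dim group's mean of, per array, the higher of its lowest signal well above background and its own signal, on the normalized log2 scale. Replicate numbers come from the labels. Deviations from the group means correlated at r 0.47 to 0.89 in all 18 pairs of the same number, 0.47 to 0.75 on slide 1. Other pairs between groups had r 0.25 to 0.65 there and -0.81 to -0.42 across slides. Some pairing beyond slide is seen. The deviations' first component (75.3%) parted the slides. Values with a replicate block are given where they change a call or move a count by over 1.5 times.

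Lists of genes were fixed before the data were examined and tested against all other genes with limma's camera, with a preset correlation between genes of 0.01 and, as an alternative, an estimated one. They were, with the members tested of those listed, CDK inhibitors (7 of 7), G1 cyclins, CDKs and E2F (15 of 16), DNA replication (34 of 34), mitosis (29 of 33), MYC and ribosome biogenesis (28 of 28), p53 targets (23 of 25), BCL2 family and death receptors (17 of 21), BCR signaling (30 of 30), B cell activation (28 of 30), B cell transcription and identity (30 of 30), quiescence and homing (24 of 24), plasma cell program (21 of 24), unfolded protein response (24 of 25), heme, iron and oxidative stress (MARE type) (23 of 25), AP-1, small MAF and BACH family (19 of 21), glycolysis and glucose uptake (17 of 17), cholesterol synthesis (20 of 20), interferon-stimulated (21 of 24), marginal zone B markers (12 of 14), B-1 B cell markers (13 of 13), immature and transitional B markers (8 of 12), T cell markers (18 of 18), NK cell markers (11 of 13), macrophage and monocyte markers (13 of 20), neutrophil markers (11 of 14), dendritic cell markers (9 of 13) and erythroid and platelet markers (10 of 16). Also fixed before the data were examined were the groups, the comparisons, the alternatives not marked otherwise and the rule for naming genes. Named were, per comparison and among genes past the test, the 7 largest rises and 7 largest falls above background on all arrays compared and without overlap of the groups (an overlap condition not used for the response difference), the 3 highest and 3 lowest bounds, up to 4 called members of each list by adjusted p, of which some with a higher adjusted p were dropped (2 per list at most were kept for the 3 comparisons with most calls), and always 14 genes: Bach2, Cdkn1a, Cdkn1b, Cdkn1c, Cdkn2a, Cdkn2b, Cdkn2c, Cdkn2d, Ccnd2, Ccnd3, Myc, Mki67, Prdm1 and Hmox1. Some results of this rule are not reported here. Clones, predicted loci and receptor segments were left out of the first parts. Symbols in parentheses after a count of 5 or fewer list members were chosen after their values were seen.

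Alternatives were quantile normalization, normexp background correction (offset 50, on the median signal, the mean signal named for it before the data were examined being not used here), no filter, only genes above background on all 12 arrays, the deposited log2 values, outlier spots kept, no floor, the mean of a gene's probes, every probe on its own, a block for the slide or the replicate number, a robust variance trend, only the compared groups fitted, an estimated correlation, and each array left out in turn. Where an array is left out, the spread is pooled over the groups. On simulated data for the 22751 genes, with 67, 67 and 66 genes changed by 1, 2 and 3 (log2), the fit recovered 17.9%, 62.7% and 78.8% at 24 h (3 unchanged genes called), 13.4%, 56.7% and 77.3% in the Bach2-/- response (8) and 0%, 23.9% and 56.1% in the response difference (1). With the replicate block 53.7%, 94.0% and 97.0% were recovered at 24 h (5). A simulated 0.5 shift of the DNA replication list at 24 h gave camera adjusted p = 3.26e-08 (0 other lists called). Real correlation between genes was not tested.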

Results

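Gene expression was measured in follicular B cells from the spleens of WT mice and of mice without Bach2 (Bach2-/-), a transcriptional repressor of the BTB and bZIP family. Cells were profiled before culture (0 h) and after 24 h with 10 µg/mL of anti-IgM Fab', which engages the B cell receptor (BCR). The series asks why Bach2-/- follicular B cells proliferate poorly after this stimulus. Each of the 4 groups held 3 arrays, 12 in all, each with 62976 spots for 55681 noncontrol probes. The 75th percentile of the processed signal ran from 97.3 on Bach2-/- 24 h array 2 to 358 on Bach2-/- 24 h array 1, and 50.9% to 66.7% of the noncontrol spots were well above background. The number of arrays limits the precision. The labels do not say that the replicates were separate animals or cultures, so the p-values measure only the spread between these samples, which may be technical. Slide 2, scanned on another day than slide 1, held array 1 of every group (4 arrays), and slide 1 held arrays 2 and 3 (8 arrays). Differences are given on the log2 scale ± standard error (n = 3 arrays per group), with limma adjusted p over 22751 genes. Medians bounded have dim genes at their bound, and counts over the list alone have p adjusted within it. A list's pair of adjusted p has the preset and then an estimated correlation. Arrays left out are named without the time or genotype that a comparison shares. A range given beside a lost call is that of the adjusted p over all alternatives. Bach2-/- 0 h array 1, without signal of Y-linked genes, and Bach2-/- 24 h array 2, the dimmest, are called the doubted arrays.

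Bach2 itself was lower on every Bach2-/- array by its reported probe. Relative to each array's 75th percentile, its log2 signal was 3.99, 3.40 and 3.69 on the WT 0 h arrays and 3.71, 3.22 and 3.69 on the WT 24 h arrays. In Bach2-/- cells it was 1.33, 0.96 and 1.11 at 0 h and 0.15, -0.86 and 0.064 at 24 h. The difference between genotypes was -2.56 ± 0.30 at 0 h (adjusted p = 0.0024) and -3.75 ± 0.30 at 24 h (adjusted p = 5.54e-05). Where the probe lies relative to the deleted part of the gene is not given in the sources used here. Another Bach2 probe was well above background on all 6 WT arrays and on 0 of the Bach2-/- arrays, so it gives no change within Bach2-/- cells. The reported probe changed by -0.15 ± 0.30 in WT cells (adjusted p = 0.806) and fell in Bach2-/- cells (-1.35 ± 0.30, adjusted p = 0.0114). Bach2 (range 0.000168 to 0.502) lost its call with the mean of a gene's probes (0.502), only the compared groups fitted (0.0594) or both doubted arrays left out (0.0623). The changes differed by -1.20 ± 0.43 (adjusted p = 0.512, and 0.026 with the replicate block).

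**Figure D1:**
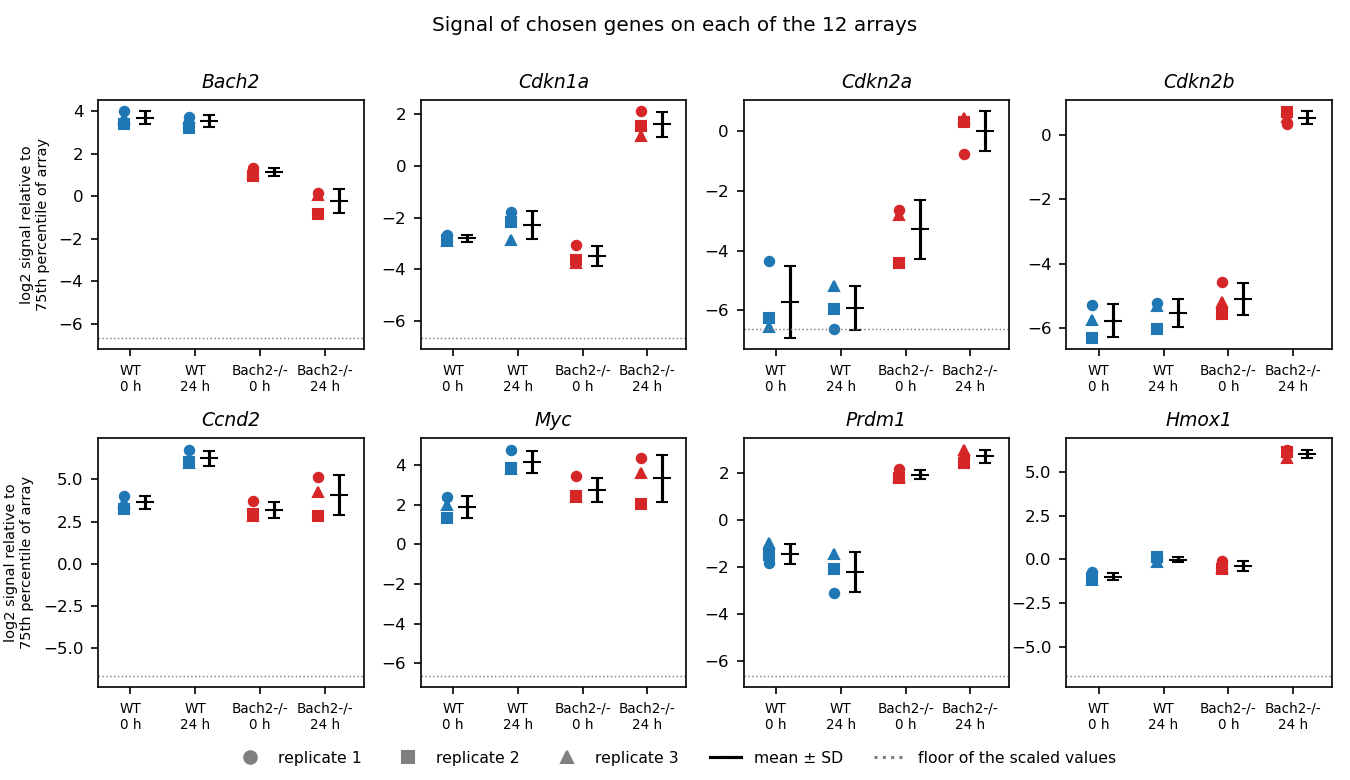
Log2 signal relative to each array's 75th percentile (vertical axis) of 8 genes on every array, with the group mean ± SD. Circles, squares and triangles are arrays 1, 2 and 3 of a group, the dotted line is the floor, and Hmox1 and Cdkn1a lie above WT on all 3 Bach2-/- arrays at 24 h.

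The comparison at 0 h asked how the genotypes differed before stimulation. Here 3 of 21 plasma cell program genes, 4 of 13 B-1 markers and 4 of 12 marginal zone markers were higher in Bach2-/- cells. Prdm1, which encodes the driver of plasma cell differentiation Blimp-1, was higher by 3.39 ± 0.39, and the plasma cell surface antigen gene Ly6c1 (2.38 ± 0.29) was higher too. The B-1 cell regulator Bhlhe41 (2.36 ± 0.27) and the phosphatase gene Ptpn22 (2.24 ± 0.25) were higher. So was S1pr3 (2.61 ± 0.25), a sphingosine-1-phosphate receptor of marginal zone B cells. Large rises were in Lilrb4a (7.18 ± 0.47), an inhibitory receptor gene, Cln8 (5.39 ± 0.32), S100a6 (5.34 ± 0.42) and S100a4 (3.48 ± 0.48), Slc39a4 (4.83 ± 0.37), Asb2 (4.59 ± 0.46) and Rbm47 (3.65 ± 0.25). The macrophage marker Ms4a7 (3.16 ± 0.38) was higher as well. The adjusted p of these 13 genes was 4.73e-05 to 0.00646. Txlnb (at least 7.27-fold), Fbp1 (at least 7.26-fold) and Rab3il1 (at least 3.28-fold) were not well above background on any WT 0 h array, and their differences are bounds with adjusted p of 0.000228 to 0.00633. Txlnb, Fbp1 and Rab3il1 lost their calls with normexp, with adjusted p of 0.265, 0.608 and 1 (ranges 2.94e-05 to 0.265, 0.00089 to 0.608 and 3e-04 to 1).

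Lower in Bach2-/- cells at 0 h, besides Bach2, were Pcp4 (-2.92 ± 0.26) and Klra16 (-2.55 ± 0.32), Cdkl1 (-2.22 ± 0.25), Crip3 (-2.10 ± 0.31), the cytokine gene Il18 (-2.03 ± 0.36) and Smpd3 (-2.01 ± 0.35). Their adjusted p was 0.000295 to 0.0273. Gatm was not well above background on any Bach2-/- array and was at least 1.87-fold lower (adjusted p = 0.00989). Cdkl1 lost its call with normexp (adjusted p = 0.109, range 0.000184 to 0.109). Crip3 (range 0.00151 to 0.0673) lost its call with normexp (0.0671) or slide 1 alone (0.0673), or without WT array 3 (0.06). Il18 (range 0.00114 to 0.125) lost its call with quantile normalization (0.104), normexp (0.0789), no filter (0.0523) or slide 1 alone (0.0926), or without any 1 of the 6 arrays (0.0811 to 0.125). Smpd3 (range 0.00543 to 0.452) lost its call with normexp (0.452), or without any array but Bach2-/- array 1 (0.09 to 0.123). Gatm (range 0.00226 to 1) lost its call with normexp (1), or without any array but WT array 1 or Bach2-/- array 1 (0.0536 to 0.061).

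The CDK inhibitor and cyclin genes did not pass the test at 0 h. The differences were Cdkn1a (-0.69 ± 0.34), Cdkn1b (-0.49 ± 0.21), Cdkn1c (-0.74 ± 0.31), Cdkn2a (2.43 ± 0.66), Cdkn2c (-0.061 ± 0.31) and Cdkn2d (-0.54 ± 0.23) for the inhibitors and Ccnd2 (-0.48 ± 0.51) and Ccnd3 (0.057 ± 0.22) for the D cyclins. Myc (0.88 ± 0.56), Mki67 (1.17 ± 0.38) and Hmox1 (0.60 ± 0.23) did not pass it either, and the adjusted p of these 11 genes was 0.21 to 1. Cdkn2a was well above background on 1 of 3 WT arrays, and Cdkn2b on 0 of 3 WT and 1 of 3 Bach2-/- arrays, so that it has no fold here.

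In all, 143 genes passed the test at 0 h, 122 higher and 21 lower in Bach2-/- cells. On all 143 of them the 3 arrays of each genotype did not overlap, as on 12.1% of all genes, where chance gives 10%. With the replicate number as a block, 849 genes passed (638 higher and 211 lower), and with the slide as a block 727 (547 and 180). The share of higher genes was 85.3%, against 75.2% with either block. Without overlap the sign on each slide is fixed. Slide 1 alone called 151. Counts fell when 1 array was left out, to 93, 69 and 61 without WT arrays 1, 2 and 3 and 75, 89 and 71 without Bach2-/- arrays 1, 2 and 3. Without both doubted arrays 104 genes passed and 75% were higher.

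At 0 h 10 of the 27 lists passed camera's test with its preset correlation and 0 with an estimated one (1 at unadjusted p under 0.05). All 10 shifted toward higher values in Bach2-/- cells. Of 29 mitosis genes (median 0.87, adjusted p = 6.94e-14 and 0.454), 0 were higher and 0 lower, against 15 and 0 at unadjusted p under 0.05 and 5 and 0 with the replicate block. Of 13 B-1 B cell marker genes (median 0.85, adjusted p = 2.29e-07 and 0.441), 4 were higher (Ptpn22, Bhlhe41, Spn and Ahr) and 0 lower, against 6 and 0 over the list alone. Of 21 plasma cell program genes (median 0.28, adjusted p = 9.61e-05 and 0.527), 3 were higher (Prdm1, Ly6c1 and Cd9) and 0 lower, against 4 and 0 over the list alone and 7 and 0 with the replicate block. Of 12 marginal zone B marker genes (median 0.15, adjusted p = 0.002 and 0.454), 4 were higher (S1pr3, Asb2, Marcks and Cd9) and 0 lower, against 5 and 1 over the list alone and 5 and 1 with the replicate block. Of 23 heme, iron and oxidative stress genes (median 0.29, adjusted p = 9.61e-05 and 0.454), 0 were higher and 0 lower, against 5 and 0 at unadjusted p under 0.05 and 4 and 0 with the replicate block. Of members named, calls ended for Spn and Ahr without any array but WT array 1 or Bach2-/- array 2, Cd9 and Marcks without any 1 of the 6 arrays (adjusted p 0.0504 to 0.177). The marginal zone B marker list lost its call with the replicate block (adjusted p = 0.0562, range 1.28e-05 to 0.643). On slide 1 alone the marginal zone median was -0.011 and on slide 2 alone 0.48, while the other 9 lists had 1 sign on both. Of markers of other cell types, the neutrophil list (median 2.14, adjusted p = 3.09e-06 and 0.454) and the erythroid and platelet list (median 0.79, adjusted p = 0.00128 and 0.454) were higher too. No member of either passed the test over all genes (5 of 11 and 3 of 10 were higher at unadjusted p under 0.05, and 5 and 3 over the list alone, 4 and 3 with the replicate block). The neutrophil median was 1.68 bounded. The MYC and ribosome biogenesis, unfolded protein response and cholesterol synthesis lists passed at adjusted p of 0.00319 to 0.0352 and lost their calls without WT 0 h array 2 or Bach2-/- 0 h array 1, the last also without WT 0 h array 3 (adjusted p 0.0563 to 0.242, 0.0655 to 0.221 and 0.134 to 0.604, ranges 5e-05 to 0.699, 0.000168 to 0.699 and 0.000714 to 0.699). With the replicate block, the BCL2 family (adjusted p = 0.0391), quiescence (0.0316, downward) and glycolysis (0.0326) lists passed too. With an estimated correlation as well they did not (0.643, 0.282 and 0.643). More lists passed upward (adjusted p), G1 cyclin (0.0483) without WT array 1, BCL2 family (0.0177 to 0.022) without WT array 1 or Bach2-/- array 2, glycolysis (0.0374 to 0.0474) without WT array 1 or Bach2-/- array 3, AP-1 (0.0153 to 0.0302) without WT array 3 or Bach2-/- array 1 or 2, macrophage (0.0289) without WT array 3 and B cell activation (0.0481) without Bach2-/- array 2. Passing downward were T cell (0.00217 to 0.0457) without WT array 1 or Bach2-/- array 1, quiescence (0.0168 to 0.0296) without WT array 2 or Bach2-/- array 1 and B cell identity (0.0141) and interferon (0.00602) without Bach2-/- array 1. Median, mean and test differed in sign for the CDK inhibitor (-0.49, 0.084, down), B cell activation (-0.098, 0.20, up), B cell identity (0.026, -0.036, down), immature B (0.13, -0.084, down) and NK cell (-0.059, 0.037, down) lists.

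The comparison after 24 h of anti-IgM asked how the genotypes differed in stimulated cells. Of 7 genes of inhibitors of cyclin-dependent kinases (CDKs) 3 were higher in Bach2-/- cells, as were 6 of 23 heme and oxidative stress genes, and Ccnd2, which encodes cyclin D2, was lower. Cdkn1a was higher by 3.87 ± 0.34 (adjusted p = 8.21e-05). Cdkn2b was at least 31.6-fold higher (adjusted p = 4.48e-06) and Cdkn2a at least 21.6-fold (adjusted p = 0.000442), neither being well above background on any WT 24 h array. Hmox1, which encodes heme oxygenase 1, showed the largest rise among genes past the test and well above background on all 6 arrays, 6.04 ± 0.23 (adjusted p = 4.43e-07), and Prdm1 was higher by 4.94 ± 0.39 (adjusted p = 4.82e-05). Bach2-/- cells also had more signal of Lilrb4a (5.63 ± 0.47) and Lilr4b (5.62 ± 0.58), Rgs16 (5.58 ± 0.28), Serpinb6b (5.49 ± 0.39), S100a6 (5.36 ± 0.42) and Rbm47 (5.23 ± 0.25). Others higher were Ly6c1 (3.25 ± 0.29), Cd9 (2.96 ± 0.30), Asb2 (4.09 ± 0.46), Ptpn22 (2.79 ± 0.25) and Bhlhe41 (2.43 ± 0.27), Chac1 (2.87 ± 0.34), the interferon-induced gene Oasl1 (3.21 ± 0.30) and the receptor genes Il2rb (4.62 ± 0.29) and Ccr9 (3.88 ± 0.43). The adjusted p of the 18 genes with values ran over 4.43e-07 to 0.000677. Plau (at least 83.8-fold), Me1 (at least 2.90-fold) and Rsad2 (at least 4.72-fold) had only bounds, with adjusted p of 1.24e-06 to 7.74e-05. Asb2 was well above background on 1 of the 3 WT 24 h arrays. Me1 and Rsad2 lost their calls with normexp, with adjusted p of 0.226 and 0.194 (ranges 3.85e-07 to 0.226 and 2.47e-05 to 0.194).

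Lower in Bach2-/- cells at 24 h, besides Bach2, were Nod1 (-3.33 ± 0.39), the Notch target Hes5 (-2.86 ± 0.42), the interleukin 5 receptor gene Il5ra (-2.68 ± 0.30), Kynu (-2.55 ± 0.49), Ell3 (-2.53 ± 0.38) and Sema3b (-2.43 ± 0.44) and Ccnd2 (-2.18 ± 0.51), with adjusted p of 0.000442 to 0.0437. Igf2bp3 (at least 4.85-fold), Grm6 (at least 3.49-fold) and Spns2 (at least 3.12-fold) were lower by bounds (adjusted p 0.00638 to 0.0263), none being well above background on any Bach2-/- 24 h array. The other CDK inhibitors did not pass the test, with Cdkn1b (-0.68 ± 0.21), Cdkn1c (-0.92 ± 0.31), Cdkn2c (-0.37 ± 0.31) and Cdkn2d (-0.63 ± 0.23). Neither did Ccnd3 (-0.41 ± 0.22), Myc (-0.83 ± 0.56) and Mki67 (1.17 ± 0.38), and the adjusted p of these 7 genes was 0.146 to 0.71. With the replicate block, Cdkn1b, Cdkn1c, Cdkn2d and Mki67 (adjusted p = 0.0188, 0.0489, 0.038 and 0.0283) passed. Kynu (range 0.000145 to 0.284) lost its call with normexp (0.284) or only the compared groups fitted (0.0596), or without Bach2-/- array 3 (0.0783). Ccnd2 (range 0.00153 to 0.189) lost its call with normexp (0.0538), no filter (0.07), genes above background on all 12 arrays (0.0541), only the compared groups fitted (0.189) or both doubted arrays left out (0.0739), or without any array but Bach2-/- array 1 (0.0967 to 0.164). Igf2bp3 (range 0.00316 to 0.347) lost its call with normexp (0.347) or slide 1 alone (0.0862), or without WT array 3 (0.0571). Grm6 (range 0.00178 to 0.682) lost its call with normexp (0.682) or only the compared groups fitted (0.0508). Spns2 (range 0.00218 to 0.902) lost its call with normexp (0.902) or only the compared groups fitted (0.168), or without any array but Bach2-/- array 1 or 2 (0.0703 to 0.0889).

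At 24 h 682 genes passed the test, 492 higher and 190 lower in Bach2-/- cells, 663 of them by at least 2-fold. On all 682 the arrays of the genotypes did not overlap, as on 15.4% of all genes (10% by chance). With the replicate block 4246 genes passed, 1816 higher and 2430 lower, and with the slide block 3472, 1521 and 1951. The share of higher genes was 72.1% without a block, 42.8% and 43.8% with them, and 86.4% of 294 genes with only the compared groups fitted. Slide 1 alone called 821. Leaving out 1 array gave 441, 420 and 361 without WT arrays 1, 2 and 3 and 419 without Bach2-/- array 3. Without both doubted arrays 560 passed.

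At 24 h 17 of the 27 lists passed camera's test, and 0 with an estimated correlation (6 at unadjusted p under 0.05). The MYC and DNA replication lists shifted lower in Bach2-/- cells and the mitosis list higher. Of 7 CDK inhibitor genes (median -0.37, adjusted p = 0.0459 and 0.275), 3 were higher (Cdkn2b, Cdkn1a and Cdkn2a) and 0 lower, against 3 and 3 over the list alone and 3 and 3 with the replicate block. Of 28 MYC and ribosome biogenesis genes (median -0.73, adjusted p = 3.54e-08 and 0.372), 0 were higher and 0 lower, against 0 and 8 at unadjusted p under 0.05 and 0 and 17 with the replicate block. Of 34 DNA replication genes (median -0.81, adjusted p = 1.07e-06 and 0.395), 0 were higher and 0 lower, against 0 and 8 at unadjusted p under 0.05 and 0 and 15 with the replicate block. Of 29 mitosis genes (median 0.84, adjusted p = 8.44e-08 and 0.372), 2 were higher (Ube2c and Ccnb2) and 0 lower, against 4 and 0 over the list alone and 11 and 0 with the replicate block. Of members named, calls ended for Ube2c without WT array 2 or Bach2-/- array 3, Ccnb2 without WT array 1 or 2 or Bach2-/- array 3 (adjusted p 0.0609 to 0.0831). The CDK inhibitor list is the study's own, named in its title, and in no comparison independent evidence. The CDK inhibitor list (range 0.00923 to 0.924) lost its call with quantile normalization (0.0751), no filter (0.0619), the mean of a gene's probes (0.0575), the slide block (0.145), the replicate block (0.187) or slide 1 alone (0.0501), or without WT array 2 or Bach2-/- array 1 or 3 (0.0531 to 0.0991). That list's test turned downward over genes above background on all 12 arrays (median -0.50, adjusted p = 0.924). Without Bach2-/- 24 h array 2, the median over the MYC and DNA replication lists was -0.33, or -0.45 with the replicate block, against -0.73 with it.

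At 24 h, of 23 heme, iron and oxidative stress genes (median 0.84, adjusted p = 1.98e-11 and 0.115), 6 were higher and 0 lower, against 11 and 1 over the list alone and 15 and 1 with the replicate block. Of 19 AP-1, small MAF and BACH family genes (median 0.41, adjusted p = 3.38e-05 and 0.197), 7 were higher and 1 lower (Bach2). Of 24 unfolded protein response genes (median 0.71, adjusted p = 1.89e-11 and 0.197), 4 were higher (Chac1, Asns, Trib3 and Hsp90b1) and 0 lower, against 13 and 0 over the list alone and 17 and 0 with the replicate block. Of 21 interferon-stimulated genes (median 0.69, adjusted p = 1.98e-11 and 0.197), 7 were higher and 0 lower, against 9 and 0 over the list alone. Of 21 plasma cell program genes (median 0.56, adjusted p = 8.47e-08 and 0.197), 6 were higher and 1 lower (Il6ra), against 9 and 1 over the list alone and 10 and 1 with the replicate block. Of 13 B-1 B cell marker genes (median 1.24, adjusted p = 1.55e-08 and 0.115), 6 were higher and 0 lower, against 8 and 1 over the list alone and 9 and 1 with the replicate block. Of 30 B cell transcription and identity genes (median -0.44, adjusted p = 9.05e-05 and 0.395), 0 were higher and 3 lower (Cr2, Ccr6 and Pou2f2), against 1 and 8 over the list alone and 3 and 12 with the replicate block. Of members named, calls ended for Hsp90b1 and Ccr6 without any array but Bach2-/- array 2, Il6ra without Bach2-/- array 3, Pou2f2 without any 1 of the 6 arrays (adjusted p 0.053 to 0.179). The AP-1 list lost its call with genes above background on all 12 arrays (adjusted p = 0.283, range 6.98e-07 to 0.283).

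Markers of other cell types were higher in Bach2-/- cells beside all of these groups. Of 11 neutrophil marker genes (median 2.68, adjusted p = 3.6e-06 and 0.263), 1 was higher (Lcn2) and 0 lower, against 6 and 0 over the list alone and 4 and 0 with the replicate block. Of 13 macrophage and monocyte marker genes (median 1.57, adjusted p = 1.37e-09 and 0.0799), 5 were higher (Cd5l, Ms4a7, Lyz2, Marco and Clec4n) and 0 lower, against 9 and 0 over the list alone and 8 and 0 with the replicate block. Of 10 erythroid and platelet marker genes (median 1.59, or 2.01 bounded, adjusted p = 9.11e-05 and 0.182), 4 were higher (Hbb-bt, Alas2, Pf4 and Hba-a1) and 0 lower, against 5 and 1 over the list alone and 5 and 1 with the replicate block. Of 18 T cell marker genes (median 0.68, or 0.82 bounded, adjusted p = 2.44e-05 and 0.198), 3 were higher (Thy1, Cd28 and Cd8b1) and 0 lower, against 8 and 0 over the list alone and 8 and 0 with the replicate block. Of 11 NK cell marker genes (median 0.42, adjusted p = 0.000232 and 0.197), 3 were higher (Il2rb, Xcl1 and Klre1) and 0 lower, against 5 and 0 over the list alone. Of 9 dendritic cell marker genes (median 0.49, or 0.70 bounded, adjusted p = 0.00109 and 0.182), 3 were higher (Ccr9, Batf3 and Itgax) and 1 lower (Flt3), against 4 and 1 over the list alone and 5 and 1 with the replicate block. Of members named, calls ended for Lcn2 without any array but WT array 2 or Bach2-/- array 1, Lyz2 without WT array 1 or Bach2-/- array 2 or 3, Marco and Clec4n without any array but Bach2-/- array 1, Alas2 without WT array 1 or 3 or Bach2-/- array 3. They ended for Pf4 and Thy1 without any array but WT array 1 or Bach2-/- array 1, Hba-a1 without any array but WT array 2 or Bach2-/- array 2, Cd28 without any array but WT array 3, Cd8b1 without any 1 of the 6 arrays. They ended for Xcl1 without any array but WT array 1 or Bach2-/- array 2, Klre1 without any array but WT array 1, Batf3 without any array but WT array 2 or 3, Itgax without any array but WT array 3 or Bach2-/- array 1. They ended for Flt3 without any array but WT array 3 or Bach2-/- array 2 (adjusted p 0.0523 to 0.176). All 17 lists called at 24 h had 1 sign on both slides.

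The other 10 lists did not pass at 24 h, and the median, the members higher and lower, and the adjusted p follow. They were G1 cyclin (-0.33, 0 and 1, 0.192), p53 (-0.064, 2 and 0, 0.631), BCL2 family (-0.045, 0 and 0, 0.937) and BCR signaling (-0.12, 1 and 2, 0.192). Then came B cell activation (-0.20, 2 and 2, 0.631), quiescence (-0.27, 1 and 3, 0.181) and glycolysis (-0.20, 1 and 0, 0.631). Last were cholesterol (-0.099, 0 and 0, 0.937), marginal zone B marker (-0.70, or -0.92 bounded, 3 and 4, 0.631) and immature B (0.18, 0 and 2, 0.941). More lists passed upward (adjusted p), cholesterol (0.0427) without Bach2-/- array 2. Passing downward were G1 cyclin (0.0289) without Bach2-/- array 1. Median, mean and test differed in sign for the CDK inhibitor (-0.37, 1.90, up), p53 (-0.064, 0.11, up), marginal zone B marker (-0.70, 0.16, down) and immature B (0.18, -0.10, down) lists.

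**Figure D2:**
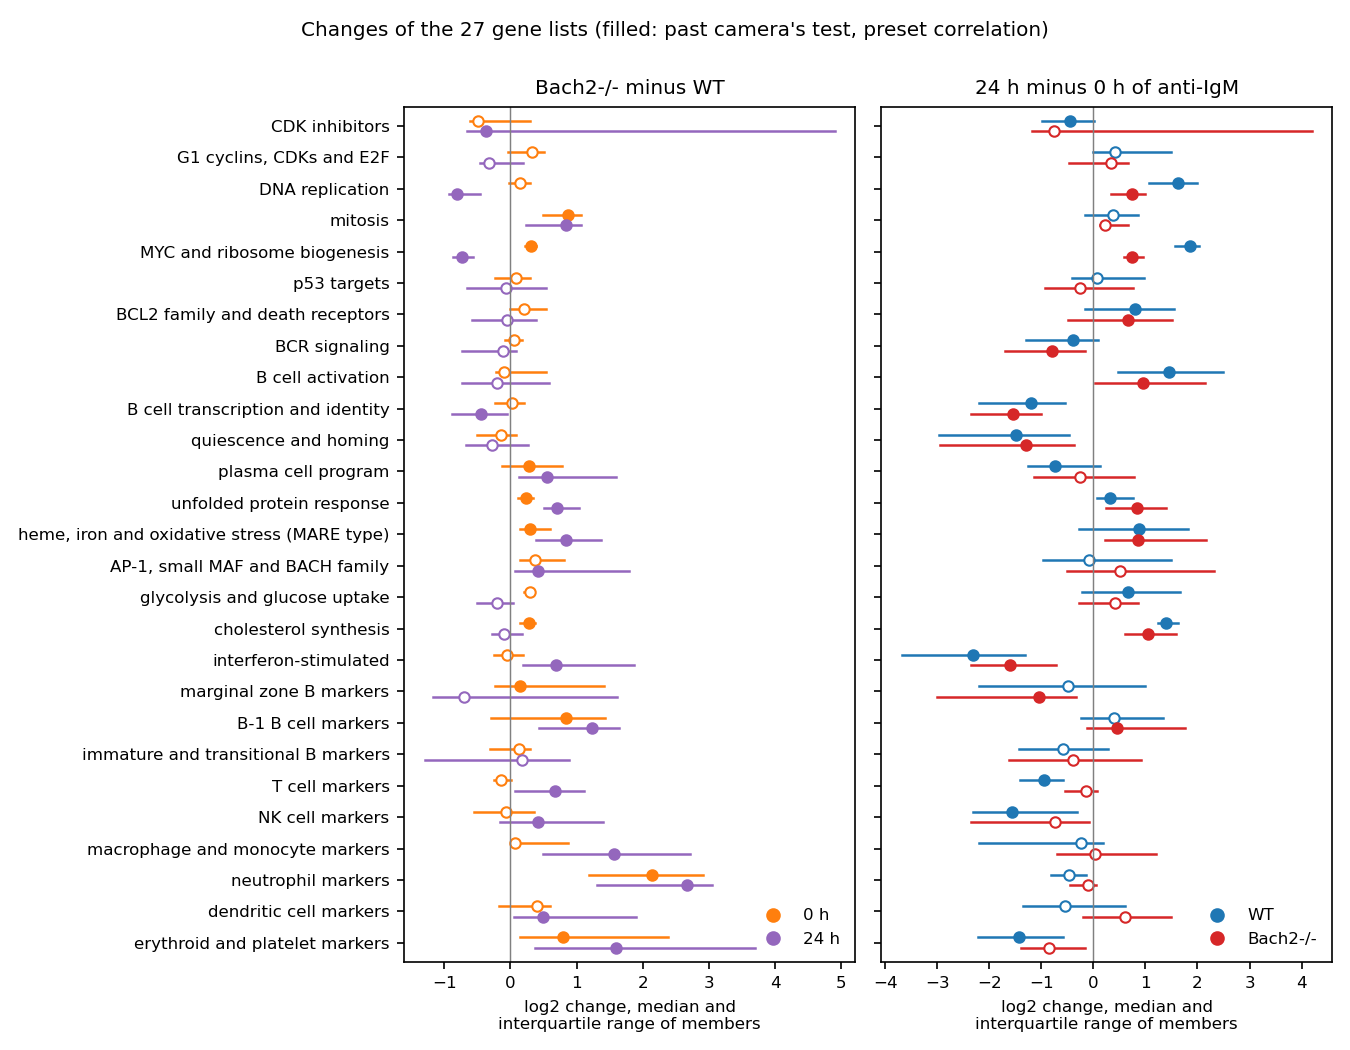
Median log2 difference (horizontal axis, with interquartile range) of the genes of 27 lists, for Bach2-/- minus WT at 0 h and 24 h (left) and for 24 h minus 0 h in WT and Bach2-/- cells (right). Filled points passed camera's test with its preset correlation, and the mitosis list lies at 0.87 and 0.84 in the left panel.

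**Figure D3:**
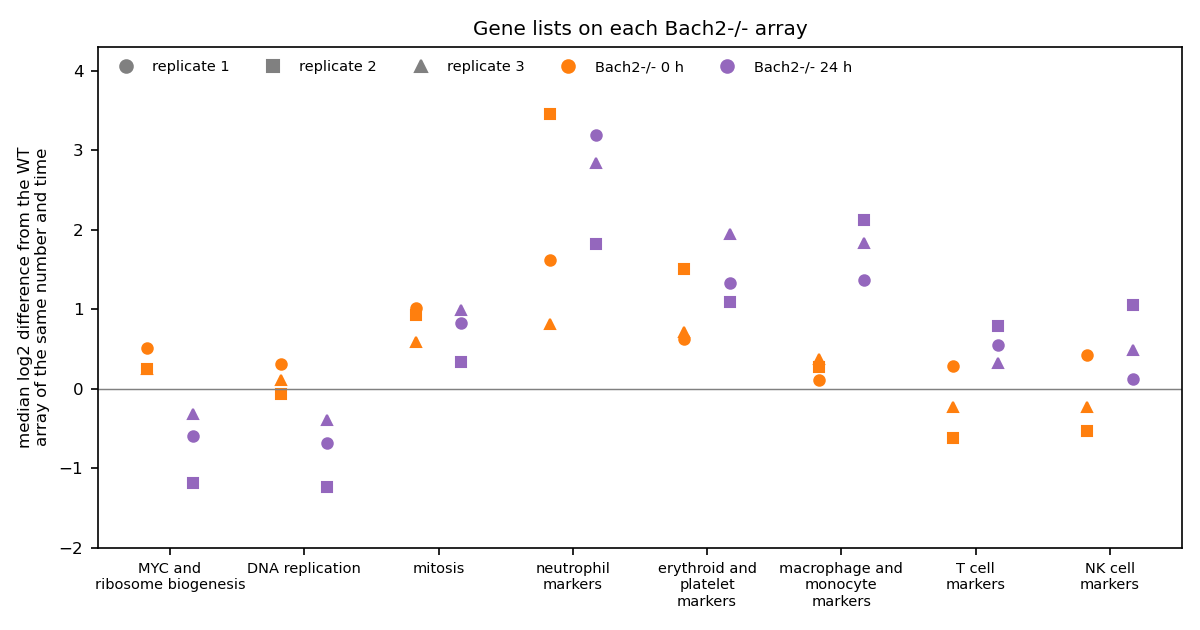
Median log2 value of the genes of 8 lists on each Bach2-/- array minus the WT array of the same number and time (vertical axis), 1 point per array. At 24 h the mitosis median was 0.83, 0.33 and 0.99 on arrays 1, 2 and 3.

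The comparison of 24 h with 0 h in WT cells asked what changed over culture with anti-IgM where Bach2 was intact. No group was cultured without anti-IgM, so effects of the culture and of the stimulus cannot be told apart. Most MYC target and DNA replication genes rose, and most interferon-stimulated, quiescence and homing genes fell. Among the D cyclin, MYC and CDK inhibitor genes, Ccnd2 (2.61 ± 0.51) and Myc (2.28 ± 0.56) rose (adjusted p = 0.00432 and 0.0138), and the inhibitors Cdkn2d (-2.47 ± 0.23) and Cdkn1b (-1.26 ± 0.21) fell (adjusted p = 4.27e-05 and 0.00166). Large rises were in the chemokine gene Ccl4 (7.71 ± 0.36), Ifitm2 (6.66 ± 0.49) and Hic1 (6.17 ± 0.37), Tubb6 (6.01 ± 0.42), Tacc2 (5.79 ± 0.30), Tnfsf14 (5.36 ± 0.50) and the interleukin 2 receptor gene Il2ra (5.12 ± 0.37). Egr2 (4.66 ± 0.24), Bcl2l1 (4.43 ± 0.29), Nop58 (1.94 ± 0.26), Tfrc (2.71 ± 0.38), Chac1 (3.66 ± 0.34), the aryl hydrocarbon receptor gene Ahr (4.13 ± 0.34) and Hmox1 (0.98 ± 0.23) rose as well. The adjusted p of these 14 genes was 1.5e-06 to 0.0128. Pdgfa (at least 61.2-fold), Rbpms2 (at least 24.2-fold) and Cyp1a1 (at least 23.5-fold) rose from below background (adjusted p 2.32e-06 to 4.13e-05). Hmox1 (range 0.000451 to 0.121) lost its call with normexp (0.0695) or the mean of a gene's probes (0.121), or without 0 h array 3 (0.0616). Myc (range 0.000181 to 0.0572) lost its call without 0 h array 2 or 24 h array 1 (0.057 to 0.0572).

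Large falls in WT cells were in Cacna1i (-6.19 ± 0.38), Ltb (-5.47 ± 0.32), Spns2 (-5.15 ± 0.35), Icosl (-5.02 ± 0.24), Abcg1 (-4.76 ± 0.25) and Vpreb3 (-4.57 ± 0.43) and Cd2 (-4.56 ± 0.24). The quiescence factor gene Klf2 (-3.66 ± 0.23), the complement receptor gene Cr2 (-3.99 ± 0.27) and the interferon-induced Oasl2 (-4.00 ± 0.28) fell too, and the adjusted p of these 10 genes was 1.53e-06 to 4.13e-05. Tmprss13 (at least 16.4-fold) and Lifr (at least 13.2-fold) fell below background (adjusted p 2.3e-06 to 2.32e-06). Cdkn1a (0.54 ± 0.34), Cdkn1c (-0.71 ± 0.31), Cdkn2c (-0.45 ± 0.31), Ccnd3 (-0.25 ± 0.22), Mki67 (-0.15 ± 0.38) and Prdm1 (-0.78 ± 0.39) did not pass the test, with adjusted p of 0.138 to 0.85, and Cdkn1a (adjusted p = 0.0293) passed with the replicate block. Cdkn2a and Cdkn2b were not well above background on any WT 24 h array and have no fold here (adjusted p = 0.884 and 0.705).

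In WT cells 4667 genes passed the test, 2606 rising and 2061 falling, and the arrays of the times did not overlap on 4651 of them, as on 38.2% of all genes (10% by chance). Blocking by replicate gave 10686 (6289 and 4397), and by slide 10212. All 4667 kept their sign on slide 1, fixed for the 4651 without overlap. Slide 1 alone called 6185, and the count was 2891 without 0 h array 3. Without both doubted arrays, 5702 passed.

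In the WT response 17 of the 27 lists passed camera's test, and 0 with an estimated correlation (2 at unadjusted p under 0.05). Of 28 MYC and ribosome biogenesis genes (median 1.86, adjusted p = 2.93e-14 and 0.346), 26 rose and 0 fell, against 27 and 0 over the list alone. Of 34 DNA replication genes (median 1.62, adjusted p = 2.9e-10 and 0.349), 22 rose and 0 fell, against 27 and 0 over the list alone. Of 21 interferon-stimulated genes (median -2.31, adjusted p = 2.93e-14 and 0.346), 1 rose (Ifih1) and 18 fell. Of 24 quiescence and homing genes (median -1.49, adjusted p = 2.74e-10 and 0.346), 1 rose (Klf9) and 16 fell, against 3 and 17 with the replicate block. Of 7 CDK inhibitor genes (median -0.45, or -0.71 bounded, adjusted p = 0.0473 and 0.349), 0 rose and 2 fell (Cdkn2d and Cdkn1b), against 1 and 2 with the replicate block. Member calls ended for Klf9 without any array but 0 h array 1 (adjusted p 0.0558 to 0.127). The CDK inhibitor list (range 0.0239 to 0.433) lost its call with quantile normalization (0.143), the slide block (0.112), the replicate block (0.126), only the compared groups fitted (0.0736), slide 1 alone (0.164) or both doubted arrays left out (0.0621), or without 0 h array 1 or 24 h array 2 or 3 (0.0539 to 0.122). The quiescence and homing list kept its call with the replicate block and an estimated correlation (adjusted p = 0.0172, range 4.47e-14 to 0.346). Markers of other cells fell beside these groups, with list values for T cell markers (median -0.96, adjusted p = 1.32e-05 and 0.346), NK cell markers (median -1.56, adjusted p = 0.00106 and 0.346) and erythroid and platelet markers (median -1.42, adjusted p = 0.00666 and 0.346). The last 2 lost their calls with normexp (0.0817 and 0.0533) or genes above background on all 12 arrays (0.0714 and 0.0599, ranges 0.000276 to 0.479 and 0.00198 to 0.346). The other 9 lists called had adjusted p of 2.74e-10 to 0.0473. Of these, the BCL2 family, unfolded protein response and glycolysis lists lost their calls with the replicate block (adjusted p = 0.0536, 0.0536 and 0.0594, ranges 0.000169 to 0.543, 0.00295 to 0.633 and 0.00451 to 0.633). The last 2 lost them also without 0 h array 2 or 24 h array 1 (0.0513 to 0.107) and 0 h array 2 or 3 or 24 h array 1 (0.0513 to 0.153). More lists passed upward (adjusted p), mitosis (0.0137) without 24 h array 2. Passing downward were immature B (0.0276) without 24 h array 1 and neutrophil (0.0309) without 24 h array 2. All 17 called lists had 1 sign on both slides. Median, mean and test differed in sign for the AP-1 (-0.078, 0.063, up) list.

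Bach2-/- cells at 24 h were compared with 0 h under the same limit, that culture and stimulus cannot be told apart. Of 7 CDK inhibitor genes 3 rose here and 2 fell. Cdkn1a (5.10 ± 0.34, adjusted p = 2.43e-06) and Cdkn2a (3.28 ± 0.66, adjusted p = 0.00551) rose, as did Cdkn2b (adjusted p = 1.4e-06), well above background on 1 of the 3 Bach2-/- 0 h arrays and given without a fold, and Hmox1 (6.41 ± 0.23, adjusted p = 5.18e-08). Large rises were in Pdcd1 (8.64 ± 0.49, WT 7.55), Rgs16 (8.48 ± 0.28, WT 3.94), Cd5l (8.28 ± 0.50, WT 4.10), a macrophage marker gene, Ccl3 (8.18 ± 0.55, WT 7.64) and Ccl4 (7.78 ± 0.36), Ifng (8.02 ± 0.35, WT 4.14) and Axl (6.94 ± 0.42, WT 7.36). Egr2 (4.76 ± 0.24), Chac1 (5.23 ± 0.34), Bcl2l1 (3.76 ± 0.29) and Il2rb (3.82 ± 0.29) rose as well, and the adjusted p of these 11 genes was 4.2e-08 to 6.19e-06. Ndrg4 (at least 170-fold), Cyp1a1 (at least 156-fold) and Nqo1 (at least 131-fold) rose from below background, with adjusted p of 5.61e-08 to 2.02e-06.

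Falls in Bach2-/- cells included Cacna1i (-6.87 ± 0.38), Ltb (-6.75 ± 0.32), Icosl (-6.37 ± 0.24), Vpreb3 (-5.61 ± 0.43), Klf2 (-5.24 ± 0.23), Abcg1 (-5.09 ± 0.25) and Kbtbd11 (-5.02 ± 0.32). By other probes, Cacna1i changed by 0.58 in Bach2-/- and -0.60 in WT cells, and Kbtbd11 by 0.095 and -0.69 in Bach2-/- cells, so their falls rest on 1 probe each. Cr2 (-5.01 ± 0.27), Bank1 (-4.16 ± 0.28), the inhibitors Cdkn2d (-2.57 ± 0.23) and Cdkn1b (-1.45 ± 0.21) and Ccnd3 (-0.72 ± 0.22) fell too, and the adjusted p of these 12 genes was 5.41e-08 to 0.0499. Fcgrt (at least 88.2-fold), Spns2 (at least 74.9-fold) and Tmprss13 (at least 29.6-fold) fell below background (adjusted p 3.24e-07 to 2.32e-05). Cdkn1c (-0.89 ± 0.31), Cdkn2c (-0.76 ± 0.31), Ccnd2 (0.91 ± 0.51), Myc (0.57 ± 0.56), Mki67 (-0.15 ± 0.38) and Prdm1 (0.77 ± 0.39) did not pass the test (adjusted p 0.0926 to 0.915), and Cdkn1c, Cdkn2c and Ccnd2 (adjusted p = 0.0354, 0.0284 and 0.0422) passed with the replicate block. Among genes not called, calls were gained (adjusted p) by Ccnd2 (0.0321) without 24 h array 2 and Cdkn2c (0.0397) without 24 h array 3. Ccnd3 (range 0.00666 to 0.179) lost its call with quantile normalization (0.0591), no filter (0.116), the deposited log2 values (0.0512), outlier spots kept (0.0506), the mean of a gene's probes (0.0638), only the compared groups fitted (0.179), slide 1 alone (0.0508) or both doubted arrays left out (0.154), or without any 1 of the 6 arrays (0.0849 to 0.138).

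In Bach2-/- cells 3016 genes passed the test, 1254 rising and 1762 falling, and the arrays of the times did not overlap on 3005 of them, as on 25.1% of all genes (10% by chance). The replicate block gave 7614 (3798 and 3816), the slide block 7061, and with only the compared groups fitted 1950. All 3016 kept their sign on slide 1, fixed for the 3005 without overlap, and slide 1 alone called 4454. Without both doubted arrays 3184 passed, of which 58.6% rose, against 41.6% with them.

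In the Bach2-/- response 13 of the 27 lists passed camera's test, and 0 with an estimated correlation (3 at unadjusted p under 0.05). Of 23 heme, iron and oxidative stress genes (median 0.85, adjusted p = 3.93e-07 and 0.354), 10 rose and 2 fell (Blvrb and Cat), against 11 and 2 over the list alone. Of 28 MYC and ribosome biogenesis genes (median 0.73, adjusted p = 5.79e-06 and 0.623), 1 rose (Tfrc) and 0 fell, against 20 and 0 with the replicate block. Of 34 DNA replication genes (median 0.73, adjusted p = 0.000462 and 0.642), 1 rose (Orc1) and 0 fell, against 0 and 0 over the list alone and 17 and 0 with the replicate block. Of 30 B cell transcription and identity genes (median -1.55, adjusted p = 9.47e-17 and 0.354), 0 rose and 20 fell, against 0 and 23 over the list alone. Of 24 quiescence and homing genes (median -1.29, adjusted p = 7.44e-11 and 0.354), 1 rose (Klf9) and 12 fell, against 2 and 15 over the list alone and 2 and 16 with the replicate block. Member calls ended for Orc1 without any array but 24 h array 2 (adjusted p 0.0555 to 0.125). The DNA replication list (range 3.85e-10 to 0.729) lost its call without 24 h array 1 (0.0511). The quiescence and homing list kept its call with the replicate block and an estimated correlation (adjusted p = 0.0121, range 2.55e-17 to 0.354). The CDK inhibitor list did not pass here (3 rose, 2 fell, adjusted p = 0.838). No list of markers of cells other than B cells passed, the lowest adjusted p among them being 0.0874 for the erythroid and platelet list (median -0.85, or -0.56 bounded). More lists passed upward (adjusted p), mitosis (0.000123 to 0.00831) without 0 h array 1 or 24 h array 2, macrophage (0.0421) without 24 h array 1 and AP-1 (0.037) and glycolysis (0.0474) without 24 h array 2. Passing downward were erythroid (0.00811 to 0.0378) without 0 h array 1 or 24 h array 3 and NK cell (0.0308) without 24 h array 2. The other 8 lists called had adjusted p of 3.82e-07 to 0.0211. The BCL2 family list (range 0.00188 to 0.743) lost its call with the slide block (0.192), the replicate block (0.233) or slide 1 alone (0.218), or without 0 h array 2 or 24 h array 1 (0.0618 to 0.159). All 13 called lists had 1 sign on both slides. Median, mean and test differed in sign for the CDK inhibitor (-0.76, 1.19, up), G1 cyclin (0.35, -0.17, down) and p53 (-0.25, 0.22, up) lists.

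The difference between the responses (Bach2-/- change minus WT change) tested whether the 24 h change differed by genotype. Here 4 of 23 heme, 2 of 7 CDK inhibitor and 3 of 21 interferon genes responded more upward in Bach2-/- cells. Hmox1 differed by 5.44 ± 0.33 and Cdkn1a by 4.56 ± 0.48, followed by Pcp4 (4.95 ± 0.37), Rgs16 (4.55 ± 0.40), Il2rb (4.33 ± 0.41), Cd5l (4.18 ± 0.71) and Oasl1 (4.16 ± 0.43). The adjusted p of these 7 genes was 6.61e-05 to 0.0339. For Cdkn2b, Me1, Srxn1 and Maf, which were not well above background on every array, only the adjusted p is given (0.000622, 0.000244, 0.00146 and 0.00384), and the response was more upward in Bach2-/- cells. Maf lost its call with normexp (adjusted p = 0.119, range 0.00126 to 0.119). Cd5l (range 0.00692 to 0.11) lost its call with quantile normalization (0.0667), no filter (0.0541), genes above background on all 12 arrays (0.0534) or slide 1 alone (0.0782), or without any array but Bach2-/- 0 h array 1 or Bach2-/- 24 h array 2 or 3 (0.0526 to 0.11). Me1 (range 2.97e-05 to 0.986) lost its call with normexp (0.986) or no filter (0.507).

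Responses lay lower in Bach2-/- cells for Prr7 (-2.97 ± 0.34), Marcks (-2.85 ± 0.32), Csf2rb2 (-2.78 ± 0.49), Dtx4 (-2.65 ± 0.44), Adora2a (-2.39 ± 0.34), Gadd45b (-2.37 ± 0.38) and Il5ra (-2.33 ± 0.42), with adjusted p of 0.0023 to 0.0494. Cdkn1b (-0.19 ± 0.30), Cdkn2c (-0.31 ± 0.44), Cdkn2d (-0.092 ± 0.33), Ccnd2 (-1.70 ± 0.72), Ccnd3 (-0.47 ± 0.31), Myc (-1.71 ± 0.79), Mki67 (0.0062 ± 0.54) and Prdm1 (1.55 ± 0.55) did not pass the test (adjusted p 0.507 to 1), and neither did Cdkn1c (adjusted p = 0.969) and Cdkn2a (adjusted p = 0.254), which were dim on some arrays. The calls of Ccnd2 and Myc in the WT response alone are thus not shown to differ between genotypes. Csf2rb2 (range 0.00113 to 0.143) lost its call with normexp (0.143), no filter (0.0752), genes above background on all 12 arrays (0.0606) or both doubted arrays left out (0.13), or without any array but WT 24 h array 2 or Bach2-/- 24 h array 1 (0.067 to 0.136). Dtx4 (range 0.00162 to 0.111) lost its call with no filter (0.0596) or both doubted arrays left out (0.0656), or without any array but WT 0 h array 1 or Bach2-/- 0 h array 1 or 2 (0.0657 to 0.111). Adora2a (range 0.00179 to 0.0807) lost its call with slide 1 alone (0.0807), or without WT 0 h array 3 or Bach2-/- 0 h array 3 (0.0527 to 0.0559). Gadd45b (range 0.000976 to 0.0926) lost its call with no filter (0.0535), slide 1 alone (0.0555) or both doubted arrays left out (0.0851), or without any array but WT 0 h array 1, WT 24 h array 2, Bach2-/- 0 h array 2 or Bach2-/- 24 h array 1 or 2 (0.051 to 0.0926). Il5ra (range 0.00163 to 0.17) lost its call with normexp (0.0886), no filter (0.102), genes above background on all 12 arrays (0.0776), the deposited log2 values (0.0576), outlier spots kept (0.0553), no floor (0.0503) or both doubted arrays left out (0.17), or without any array but WT 0 h array 1 (0.0688 to 0.164).

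The response differed between genotypes for 75 genes, 60 upward and 15 downward in Bach2-/- cells. A replicate block let 976 pass, 394 and 582, and with the slide block 783, 316 and 467. The upward share was 80%, against 40.4% with either block and 91.7% with no filter on dim probes. Of the 75, 75 kept their sign on slide 1 alone and 74 on slide 2 alone, and slide 1 alone called 99. Leaving out 1 array gave 36 without WT 0 h array 3, 37 without WT 24 h array 3 and 48 and 44 without Bach2-/- 0 h arrays 2 and 3 genes. Without both doubted arrays 85 passed.

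For the response difference 14 of the 27 lists passed camera's test, and 0 with an estimated correlation (4 at unadjusted p under 0.05). Of 7 CDK inhibitor genes (median -0.092, adjusted p = 0.000246 and 0.234), 2 responded more upward (Cdkn2b and Cdkn1a) and 0 more downward, against 3 and 0 over the list alone. Of 23 heme, iron and oxidative stress genes (median 0.32, adjusted p = 1.89e-05 and 0.319), 4 responded more upward (Hmox1, Me1, Srxn1 and Nqo1) and 0 more downward, against 5 and 0 over the list alone. Of 21 interferon-stimulated genes (median 0.51, adjusted p = 2.92e-11 and 0.305), 3 responded more upward (Oasl1, Isg15 and Rsad2) and 0 more downward, against 7 and 0 over the list alone and 7 and 0 with the replicate block. Of 28 MYC and ribosome biogenesis genes (median -0.998, adjusted p = 3.44e-11 and 0.405), 0 responded more upward and 0 more downward, against 0 and 7 at unadjusted p under 0.05 and 0 and 6 with the replicate block. Of 34 DNA replication genes (median -0.81, adjusted p = 5.8e-07 and 0.492), 0 responded more upward and 0 more downward, against 0 and 3 at unadjusted p under 0.05 and 0 and 2 with the replicate block. Member calls ended for Nqo1 without any array but WT 24 h array 1, Bach2-/- 0 h array 1 or Bach2-/- 24 h array 2, Isg15 without any array but WT 0 h array 2, Bach2-/- 0 h array 1 or Bach2-/- 24 h array 2, Rsad2 without any array but WT 0 h array 2, Bach2-/- 0 h array 1 or Bach2-/- 24 h array 1, 2 or 3 (adjusted p 0.0508 to 0.0907). The CDK inhibitor list lost its call with genes above background on all 12 arrays (adjusted p = 0.103, range 9.61e-06 to 0.399). The DNA replication list lost its call with both doubted arrays left out (adjusted p = 0.0608, range 1.92e-11 to 0.492). The CDK inhibitor median was 0.12 on slide 1 and 0.31 on slide 2. Markers of other cells responded more upward in Bach2-/- cells, with list values for T cell markers (median 1.08, adjusted p = 1.1e-06 and 0.305), macrophage and monocyte markers (median 1.38, adjusted p = 2.43e-05 and 0.234) and NK cell markers (median 0.20, adjusted p = 0.00105 and 0.319). The NK cell median was 0.54 on slide 1 and -0.18 on slide 2, and the other 12 lists had 1 sign on both. The other 6 lists called had adjusted p of 4.07e-06 to 0.0379. Of these, the AP-1 list lost its call with the replicate block (adjusted p = 0.0973) or without WT 0 h array 1 or 3, WT 24 h array 3, Bach2-/- 0 h array 1 or 2 or Bach2-/- 24 h array 1 (0.0659 to 0.27), and the G1 cyclin list without WT 0 h array 2, WT 24 h array 1, Bach2-/- 0 h array 1 or Bach2-/- 24 h array 2 (0.0548 to 0.173, ranges 0.00208 to 0.845 and 0.00244 to 0.662). More lists passed upward (adjusted p), erythroid (0.0398 to 0.0431) without WT 0 h array 1, WT 24 h array 2 or Bach2-/- 0 h array 3, B-1 B cell (0.0109 to 0.0473) without WT 24 h array 1 or Bach2-/- 0 h array 1, dendritic cell (0.0109 to 0.0434) without WT 24 h array 1, Bach2-/- 0 h array 1 or Bach2-/- 24 h array 3, neutrophil (0.0369 to 0.0485) without WT 24 h array 2 or Bach2-/- 24 h array 1 and mitosis (0.00799) without Bach2-/- 24 h array 2. Passing downward were BCR signaling (0.0158 to 0.0486) without WT 0 h array 1, WT 24 h array 2 or 3, Bach2-/- 0 h array 2 or 3 or Bach2-/- 24 h array 1, cholesterol (0.0158 to 0.0468) without WT 0 h array 1, Bach2-/- 0 h array 2 or Bach2-/- 24 h array 1 or 3, BCL2 family (0.0349 to 0.0419) without WT 24 h array 2 or Bach2-/- 24 h array 1, B cell activation (0.0325 to 0.0411) without Bach2-/- 0 h array 2 or Bach2-/- 24 h array 1, glycolysis (0.0186) without Bach2-/- 24 h array 1 and mitosis (0.0434) without Bach2-/- 24 h array 3. Median, mean and test differed in sign for the CDK inhibitor (-0.092, 1.81, up), p53 (-0.22, 0.012, down), quiescence (0.017, -0.059, down) and immature B (0.39, -0.017, up) lists.

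Across genes, which are not independent replicates, the Bach2-/- response followed the WT response with Pearson r 0.76, Spearman rho 0.68 and a slope of 0.73. The compared changes share no array. Of 2606 genes that rose in WT cells and 1254 that rose in Bach2-/- cells, 853 were shared, against 144 for independent lists, and of 2061 and 1762 that fell, 1301 against 159.6. The genotype difference at 24 h followed that at 0 h with r 0.29, rho 0.080 and a slope of 0.40. Here Spearman rho was -0.061 with no filter and -0.056 without WT 0 h array 1 and 0.31 without Bach2-/- 0 h array 1. Of the 122 genes higher in Bach2-/- cells at 0 h, 71 were also higher at 24 h (expected 2.64), and of the 21 lower, 8 (expected 0.175).

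**Figure D4:**
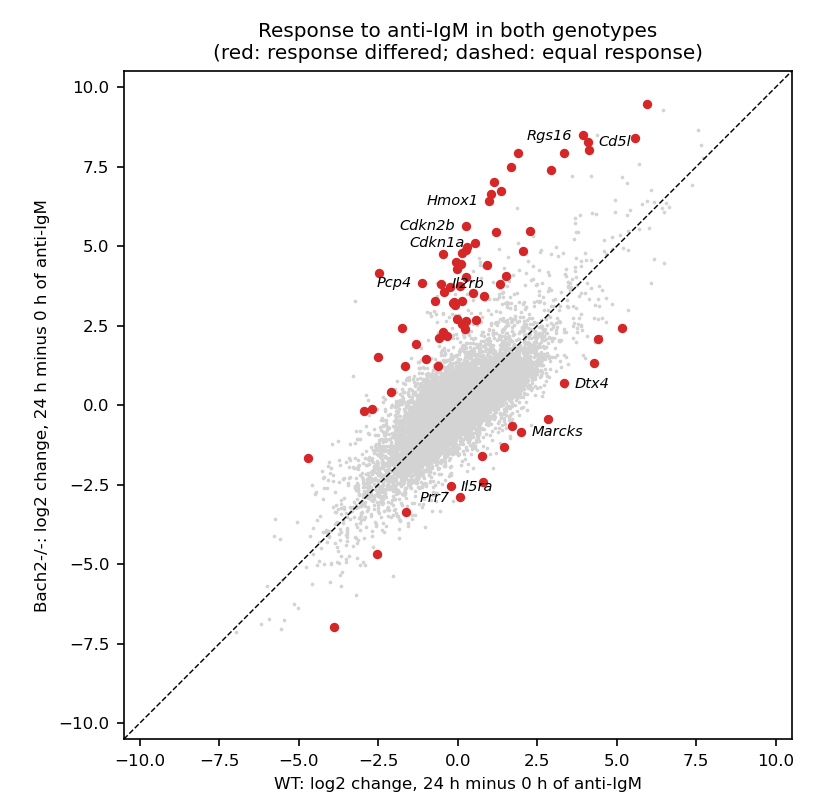
Log2 change from 0 h to 24 h in WT cells (horizontal axis) and in Bach2-/- cells (vertical axis), 1 point per gene. The dashed line marks equal responses, and the 75 red points are genes whose response differed, 60 of them above the line.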

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

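The tests of the 3 patterns below were chosen after the result was seen, and those of other splits of the arrays before. The 24 h response differed between the genotypes, by the test of the difference itself, for these named genes. The response in Bach2-/- cells minus that in WT cells was 4.18 (Cd5l), 4.56 (Cdkn1a), 5.44 (Hmox1), 3.88 (Ifng), 4.33 (Il2rb), 2.74 (Isg15), 4.16 (Oasl1), 4.95 (Pcp4) and 4.55 (Rgs16), and below 0 at -2.39 (Adora2a), -2.78 (Csf2rb2), -2.65 (Dtx4), -2.37 (Gadd45b), -2.33 (Il5ra), -2.85 (Marcks) and -2.97 (Prr7), on the log2 scale. For genes not well above background on all 12 arrays only limma's adjusted p is given, 0.000622 (Cdkn2b), 0.00384 (Maf), 0.000244 (Me1), 0.00117 (Ndrg4), 0.0274 (Nqo1), 0.00982 (Pdgfa), 0.000119 (Plau), 0.0246 (Rsad2), 0.00146 (Srxn1) and 0.0417 (Txlnb). The calls of Isg15, Nqo1 and Rsad2 ended under some alternatives (adjusted p up to 0.0815, 0.0826 and 1). List medians of the difference, where camera passed with its preset correlation, were -0.092 (CDK inhibitor), -0.50 (G1 cyclin, CDK and E2F), -0.81 (DNA replication), -0.998 (MYC and ribosome biogenesis), -0.52 (B cell transcription and identity), 0.54 (plasma cell program), 0.52 (unfolded protein response), 0.32 (heme, iron and oxidative stress), 0.092 (AP-1, small MAF and BACH family), 0.51 (interferon-stimulated), -0.68 (marginal zone B marker), 1.08 (T cell marker), 0.20 (NK cell marker) and 1.38 (macrophage and monocyte marker). None of these lists passed with an estimated correlation, the smallest adjusted p over the 27 lists being 0.234.

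Other splits of the 6 arrays of each comparison into 3 and 3 are too few (10) for a share under 0.05. The real splits gave 143, 682, 4667 and 3016 genes in the order of the report, 1 of 10 splits being as large in each case, and the highest of the others gave 0, also among the others of the 4 that part all 3 pairs. For the response difference, chance is not excluded by this count: 5 of 100 drawn exchanges of genotype labels within a time (200 possible), the real one included, gave as many as the real 75 genes, the highest 199. A breakdown added later put all 4 others among 10 that keep the 24 h labels (45 to 199). The 89 that mix genotypes at 24 h (highest 2) add their difference to the spread and decide nothing. Of 15 drawn that part all pairs at both times, too few for a share under 0.05, only the real one reached 75 (next 69).

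Markers of macrophages (median 1.57), neutrophils (2.68), T cells (0.68) and other cells were higher in Bach2-/- at 24 h in cells purified as follicular B cells, though 10 of 13 macrophage, 7 of 11 neutrophil and 17 of 18 T cell markers (1 of the last in another list) were above background on all WT 0 h arrays too. A lower share of B cells stays open. The neutrophil median exceeded that of T cells by 2, above the larger interquartile range (1.73, a bound set afterwards). This argues only against other types rising alike. Neutrophil markers were higher at 0 h too (2.14). The macrophage median without the dim array 2, 1.30 (1.33 with the replicate block), argues against that array. Macrophages in the Bach2-/- cultures may be a source and stay open, since of C1qa, C1qb and C1qc, abundant macrophage transcripts, only C1qb was above background on all 24 h arrays (0.49), and 1 gene decides nothing. Adgre1, above background on all 12 arrays, changed by -0.26 and -0.48 by its 2 probes, but WT 24 h means of 0.74 and 1.88 would hide a small share, and Mertk and Fcgr1 were above background on 0 arrays, a reading that replaced 2 others after the results were seen. Expression by Bach2-/- B cells themselves stays open and was not tested.

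The 62 genes of the MYC and ribosome biogenesis and DNA replication lists had a median of -0.73 in Bach2-/- relative to WT cells at 24 h. Slides 1 and 2 (-0.76 and -0.64) held all groups alike, so a shift between them is not tested. Quantile normalization (-0.56) argues against the scaling. The dim array 2 may account for much of the lower median and stays open. Without that array the median was -0.33, and -0.45 with the replicate block, on either side of the bound set. A genotype effect also stays open, the arrays lying at -0.60, -1.19 and -0.32 (MYC list) and -0.68, -1.23 and -0.39 (DNA replication list) relative to the WT 24 h array of the same number for arrays 1, 2 and 3.

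Bach2-/- 0 h array 1 had no signal well above background for the Y-linked Ddx3y and Eif2s3y, which the other 11 arrays had, while the labels give male mice. A swap with another group of the series would leave 2 arrays out of place, and the count of arrays nearer the median of the other genotype by Bach2 or of the other time by Klf2, 0, argues against it. That array's Bach2 value of 1.33, below the WT 0 h range of 3.40 to 3.99, argues against a WT sample under this label. Cells of a female mouse are a possible explanation that stays open, Xist being above background there (up to -0.82). Xist was above background on 6 arrays, 5 of them with both Y-linked genes, among them the 3 other arrays of the same slide.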

How the results depend on the processing

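The settings of slide 1 alone, RefSeq-named genes alone, both doubted arrays left out, an estimated correlation with the replicate block, array 2 left out with the replicate block, and the arrays left out for the relations across genes were chosen after seeing the data. Over 18 settings and each of 12 arrays left out, no named gene past the test turned its direction, and 16 of 32, 33 of 59, 61 of 70, 57 of 64 and 10 of 21 stayed past it throughout, in the order of the report. Signal over background leaves genes dim in a group with bounds alone. Normexp ended 46 calls of named genes, no filter 16, only the compared groups fitted 30, leaving out both doubted arrays 19 and slide 1 alone 19. An estimated correlation ended all 71 list calls. Of lists past the test, the direction turned only for CDK inhibitors at 24 h and for AP-1 in the response difference, in both with genes above background on all 12 arrays. The replicate block let 9 named genes and 3 lists pass, ended the calls of 8 lists and changed no other call of a named gene or list. The median of all genes moved by -0.10 at 0 h, 0.19 at 24 h, 0.15 in the Bach2-/- response and 0.26 in the response difference with no filter and 0.11 in the WT response and -0.12 in the response difference with RefSeq-named genes alone. Tested on their own, 192, 838, 6341, 4084 and 94 probes passed. Over the 18 settings, lists not past the test that turned and then passed were NK cell at 0 h over genes above background on all 12 arrays (adjusted p = 0.0258) and, without both doubted arrays, cholesterol at 24 h (0.0303) and mitosis in the response difference (2.43e-05). The cause of these changes was not tested.

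A list's direction is that of its test and the value printed is its median, so that some turned without a change of the median. The response difference is called the difference here. With RefSeq-named genes alone directions turned at 24 h for the BCL2 family (-0.045), cholesterol (-0.099) and immature B (0.18) lists, in the WT response for the AP-1 (-0.078) list and in the difference for the mitosis (-0.020), p53 (-0.22) and quiescence (0.017) lists. With genes above background on all 12 arrays 78 genes passed at 0 h, 350 at 24 h and 29 in the difference. Directions turned at 0 h for the NK cell (0.36) list, at 24 h for the BCL2 family (-0.045), CDK inhibitor (-0.50), cholesterol (-0.099) and immature B (0.18) lists, in the WT response for the AP-1 (-0.12) and dendritic cell (0.40) lists, in the Bach2-/- response for the AP-1 (0.067) and CDK inhibitor (-1.11) lists and in the difference for the AP-1 (0.0082), mitosis (-0.015) and quiescence (0.017) lists. With both doubted arrays left out directions turned at 0 h for the B cell activation (-0.21), BCR signaling (-0.15) and DNA replication (-0.080) lists, at 24 h for the B cell activation (-0.023), BCL2 family (0.11), G1 cyclin (-0.14), cholesterol (0.12), glycolysis (-0.00016) and immature B (0.38) lists, in the Bach2-/- response for Mki67 (0.36) and the G1 cyclin (0.73) and plasma cell (0.082) lists and in the difference for the B cell activation (0.22), BCL2 family (-0.065), cholesterol (0.078), glycolysis (-0.11), mitosis (0.47), neutrophil (0.021), p53 (-0.084) and quiescence (0.21) lists. With no filter 48 genes passed in the difference. Directions turned at 0 h for the NK cell (-0.15), immature B (0.26) and interferon (-0.043) lists, at 24 h for the immature B (0.34) list, in the Bach2-/- response for the CDK inhibitor (-0.76) list and in the difference for the erythroid (0.33), immature B (-0.0050) and neutrophil (0.36) lists. Across genes, r, rho and slope were then 0.64, 0.43 and 0.63 between the responses, and 0.13, -0.061 and 0.17 between the genotype differences. With normexp 62 genes passed at 0 h, 323 at 24 h and 41 in the difference. Directions turned at 0 h for the NK cell (-0.044) list, at 24 h for the immature B (0.061) list, in the WT response for Cdkn2a (0.045) and the dendritic cell (-0.092) list and in the difference for Cdkn1c (0.074) and Mki67 (-0.062) and the mitosis (-0.0097) list. With only the compared groups fitted 83 genes passed at 0 h, 294 at 24 h and 1950 in the Bach2-/- response. Directions turned at 24 h for the immature B (0.18) list. With quantile normalization 218 genes passed at 0 h. Directions turned at 0 h for Ccnd3 (-0.086) and the BCR signaling (-0.064) and NK cell (-0.080) lists, at 24 h for the B cell activation (-0.16), BCL2 family (0.064), cholesterol (0.054) and glycolysis (0.065) lists, in the Bach2-/- response for the G1 cyclin (0.31) list and in the difference for Cdkn1b (0.10) and Cdkn2d (0.19) and the BCR signaling (0.033), p53 (-0.18) and quiescence (0.19) lists. With the replicate block 849 genes passed at 0 h, 4246 at 24 h, 10686 in the WT response, 7614 in the Bach2-/- response and 976 in the difference. Directions turned, also with an estimated correlation, at 24 h for the immature B (0.18) list, in the Bach2-/- response for the G1 cyclin (0.35) and p53 (-0.25) lists and in the difference for the quiescence (0.017) list. With the deposited log2 values directions turned in the difference for Mki67 (-0.0011). With slide 1 alone directions turned at 0 h for Ccnd3 (-0.16) and the BCR signaling (-0.054) list, at 24 h for the immature B (0.15) list, in the WT response for Cdkn2a (0.84), in the Bach2-/- response for Mki67 (0.054) and the T cell (-0.012), neutrophil (0.29) and p53 (-0.24) lists and in the difference for Cdkn1b (0.053) and Cdkn2d (0.12) and the mitosis (-0.042) and quiescence (0.011) lists. With the slide block 727 genes passed at 0 h, 3472 at 24 h, 10212 in the WT response, 7061 in the Bach2-/- response and 783 in the difference. Directions turned at 24 h for the cholesterol (-0.099) and immature B (0.18) lists, in the Bach2-/- response for the p53 (-0.25) list and in the difference for the mitosis (-0.020) and quiescence (0.017) lists.

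With 1 array left out, the counts were 2891 to 3732 in the WT response, 61 to 93 at 0 h, 361 to 564 at 24 h and 36 to 75 in the response difference. Directions turned for at least 1 array as follows, with the range of values. This held at 0 h for Ccnd3 (-0.11 to 0.15) and Cdkn2c (-0.12 to 0.021) and the B cell activation (-0.21 to 0.10), B cell identity (-0.13 to 0.085), BCR signaling (-0.15 to 0.15), DNA replication (-0.080 to 0.27), NK cell (-0.31 to 0.13), T cell (-0.32 to 0.026) and interferon (-0.22 to 0.095) lists. This held at 24 h for the B cell activation (-0.56 to 0.032), BCL2 family (-0.23 to 0.11), G1 cyclin (-0.45 to -0.12), cholesterol (-0.30 to 0.12), glycolysis (-0.62 to -0.00016), immature B (-0.027 to 0.38) and p53 (-0.22 to 0.15) lists. This held in the WT response for Bach2 (-0.30 to 0.0067), Cdkn2a (-0.63 to 0.48), Cdkn2b (-0.015 to 0.50) and Mki67 (-0.47 to 0.057) and the AP-1 (-0.30 to 0.068) and neutrophil (-1.09 to 0.58) lists. This held in the Bach2-/- response for Mki67 (-0.50 to 0.18) and the CDK inhibitor (-0.93 to -0.48), G1 cyclin (-0.013 to 0.52), neutrophil (-0.66 to 0.38) and p53 (-0.38 to -0.022) lists. This held in the difference for Cdkn1c (-0.41 to 0.033), Cdkn2d (-0.21 to 0.063) and Mki67 (-0.34 to 0.34) and the cholesterol (-0.69 to -0.11), immature B (0.17 to 0.48), mitosis (-0.37 to 0.34), neutrophil (-0.40 to 1.01), p53 (-0.38 to -0.014) and quiescence (-0.20 to 0.16) lists. None of these had passed the test. Across genes r ran from 0.64 to 0.81, rho from 0.48 to 0.77 and the slope from 0.64 to 0.82 between the responses, and r from 0.18 to 0.39, rho from -0.056 to 0.31 and the slope from 0.20 to 0.52 between the genotype differences.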

Other observations

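The genes given here were chosen after their values were seen. Ifng, which encodes interferon gamma, had log2 values of 1.40, 1.25 and 0.84 on the WT 24 h arrays and 5.78, 5.39 and 5.33 on the Bach2-/- 24 h arrays, from -2.30, -3.62 and -3.02 and -2.54, -2.91 and -2.10 at 0 h. Spp1, which encodes osteopontin, stood at -0.54, -1.29 and -1.49 in WT and 1.83, 3.67 and 1.31 in Bach2-/- cells at 24 h. At 24 h both genes were well above background on all 6 arrays.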
